A study of Mus musculus with 16 samples.

How the data were processed

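Livers of mice 3 to 6 months old that were wild-type for Perk (gene symbol Eif2ak3, the endoplasmic reticulum kinase that phosphorylates eIF2 alpha) or had it deleted in liver by an albumin-driven Cre were perfused in a single pass with buffer holding 0.1 mM CaCl2, without or with tBuHQ, per the labels' protocols. tBuHQ is a di-tert-butylhydroquinone, of which the labels name different isomers, that inhibits calcium uptake into the endoplasmic reticulum and was used to disturb the folding of proteins there. RNA was taken from unfractionated liver and from the polysome part of a 20 to 47% sucrose gradient, which holds mRNA carrying several ribosomes. Each array was hybridised with RNA pooled from 2 livers, and 12 µg of RNA entered each labelling, per the labels' protocols. Crossing genotype, treatment and fraction gave 8 groups of 2 arrays, 16 in all. The labels call the 2 arrays of a group biological replicates. They do not say whether the unfractionated and the polysome array of one number came from the same livers.

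The values used were the deposited signal intensity of each of 45101 probe sets on an Affymetrix mouse array, on a linear scale. The authors had scaled every array to the same 2%-trimmed mean of 150, as the values showed, and the summarisation software and detection calls are not given in the sources used here. The authors also deposited a table with a z score for each array and 18697 probe sets, which per the file headers keeps probe sets with a raw signal of at least 80 in at least 1 of 32 conditions. Of these probe sets, 15695 reached 80 on the 16 arrays used here. The z score table entered only as an alternative and to check the labels. One pair of values from its column of z ratios is printed and credited to the authors' deposited table.

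Probe sets were named from the platform annotation. It gave 34958 probe sets 1 gene symbol, 932 several and 9211 none, and 34754 symbols were updated through their Entrez identifiers with the GRCm38.p6 gene table. A probe set with several symbols named no gene. Signals were turned to log2(signal + 16), so that differences of dim genes are understated, with no further normalization because the arrays were already scaled alike. For each gene the probe set with the highest mean over the 16 arrays was kept, and probe sets with a mean under the 40th percentile were left out, which left 12150 genes. Where probe sets of a gene disagree, only the kept one is reported. No sequence depth applies to arrays, and their number, 2 per group, limits the precision.

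Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with 8 group means fitted to all 16 arrays, 8 residual degrees of freedom and 6.98 prior degrees of freedom. The 13 contrasts were the tBuHQ effect in each genotype and fraction, its difference between genotypes in each fraction, its difference between fractions in each genotype, the difference of those differences, the genotype difference without tBuHQ in each fraction, and the difference between fractions without tBuHQ in each genotype. p-values were adjusted by Benjamini and Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. Log2 differences are given with the standard error of limma's fit. The p-values measure the spread between these arrays, each a pool of 2 livers. Chance alone would give 608 of the 12150 genes an unadjusted p under 0.05. The Perk target was tested over all 16 arrays with limma and with an exact permutation test of the arrays.

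The gene lists, the rule that names genes and the alternatives were fixed before the data were examined, except where stated. There were 32 lists on the integrated stress response (ISR), translation, the endoplasmic reticulum, metabolism, stress, the clock, other cell types of the liver or its surroundings, and sex. The 28 lists with at least 5 tested members were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, and again with the correlation estimated from the residuals. Of 132 list calls over the 13 contrasts, 3 held with an estimated correlation: gluconeogenesis and fasting genes for tBuHQ in knockout polysome RNA, and RIDD substrates and macrophage markers between the fractions of untreated wild-type liver. The cholangiocyte, lymphocyte, neutrophil and erythroid lists had fewer members and were only counted. Where a list's median, mean and camera direction differed in sign, it was not called in that contrast. Members were counted past an adjusted p of 0.05 over all genes and adjusted over the list alone.

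The naming rule took, for each contrast, the 6 largest increases and the 6 largest decreases among called genes whose arrays did not overlap between the groups (for differences of differences, among called genes), without clone or predicted names. It added up to 4 called members of each list that passed camera or had at least 3 called members, and always Eif2ak3, Atf4, Ddit3, Trib3, Asns, Ppp1r15a, Hspa5, Xbp1, Herpud1 and Alb. Where this gave over 30 genes, some list members were left out of the text. Others were chosen after their values were seen, to account for small counts: Gadd45a, Creld2, Ppara, Pdk1, Pfkfb3, Bid, Nfil3 and Csf1r for tBuHQ in wild-type unfractionated RNA, Vldlr and Rgs5 for its difference between genotypes, P4hb, Ssr3 and Lss for untreated genotypes, Rpl10a and Rps2 for untreated wild-type fractions, Hspd1 and Cyp2f2 for untreated knockout fractions. Cel, Cela1, Cela2a, Cpa1, Ctrb1, Prss2, Cyp2c50, Cyp2c54, Xist and Eif2s3y, given per array, were also chosen then.

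The alternatives were an offset of 1 or 64, no filter or a filter at the 60th percentile, quantile normalization over all arrays or within each fraction, median centring, all named probe sets, eBayes without a trend, the replicate number as a block, the pool as a random block, only the arrays of a contrast, the authors' z scores, and each array left out in turn. Removing each array's trend on gene span, the genomic distance from a gene's start to its end, was added after seeing the data. So was singling out 2 arrays, the second wild-type tBuHQ polysome array and the first knockout tBuHQ unfractionated array, whose results are those with each array left out.

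The steps were tested on simulated data with the means and spread of the real genes and 200 changed genes among 12150. The simulated noise was independent between genes and between arrays, without the shared differences between arrays seen in the real data. The false calls and list calls given here therefore do not show how many real calls are false. For tBuHQ in wild-type unfractionated RNA, 1.49% of genes changed 1.5-fold, 11.9% of genes changed 2-fold and 90.9% of genes changed 4-fold were called, with 5 false calls. For the difference between genotypes in unfractionated RNA, 48.5% of genes changed 4-fold and 0% of those changed 1.5-fold or 2-fold were called, with 2 false calls. For the 3-way difference of genotype, treatment and fraction none was called at any of these sizes. For the fractions of untreated knockout liver, 0% of 1.5-fold, 13.4% of 2-fold and 90.9% of 4-fold changes were called, with 2 false calls. A simulated shift of 0.5 on the log2 scale of the oxidative phosphorylation list was called with an adjusted p of 9.15e-25 with the preset and 1.94e-05 with an estimated correlation, with 0 other lists called. Plots were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3. Genomic positions are not printed, because the array's own annotation names no genome build.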

Results

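RNA from perfused mouse liver was measured on 16 arrays in 8 groups of 2: Perk wild-type or liver-knockout, without or with tBuHQ, in unfractionated or polysome RNA. All arrays had a trimmed mean signal of 150, with median signals of 17.1 to 22.9. The correlation across probe sets between the 2 arrays of a group ranged from 0.943 in wild-type tBuHQ polysome RNA to 0.975 in untreated wild-type unfractionated RNA, and at most 1 probe set held identical values on both. Xist, the female inactive-X transcript, stayed below a signal of 30.4 on every array, and the Y-linked gene Eif2s3y ranged from 297 to 884.

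On the second wild-type tBuHQ polysome array, the ratio of 3' to 5' probe set signals of Gapdh was 5.60, against 0.735 to 0.859 on the other 15 arrays. The beta-actin ratio was 1.98 there and 1.21 to 1.37 on the others, and that of the thr spike-in RNA was 16.3 and 0.900 to 1.29. Among the 8 unfractionated arrays, both untreated wild-type arrays and the first knockout tBuHQ array stood apart. Their correlations with one another were 0.973 to 0.975 and with the other 5 arrays 0.948 to 0.964, and their 75th percentile signals were 105 to 114, against 83.7 to 88.9. Of 6 pancreatic markers 5 read higher on the first wild-type tBuHQ array and the first untreated knockout array of both fractions than on any of the other 12 arrays. Of these Cpa1, a carboxypeptidase, read 238 and 283 in unfractionated RNA and 239 and 291 in polysome RNA there, and 1.18 to 14.9 on the other 12. The elastase Cela1, at 745 or more on every array, did not follow them.

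**Figure D1:**
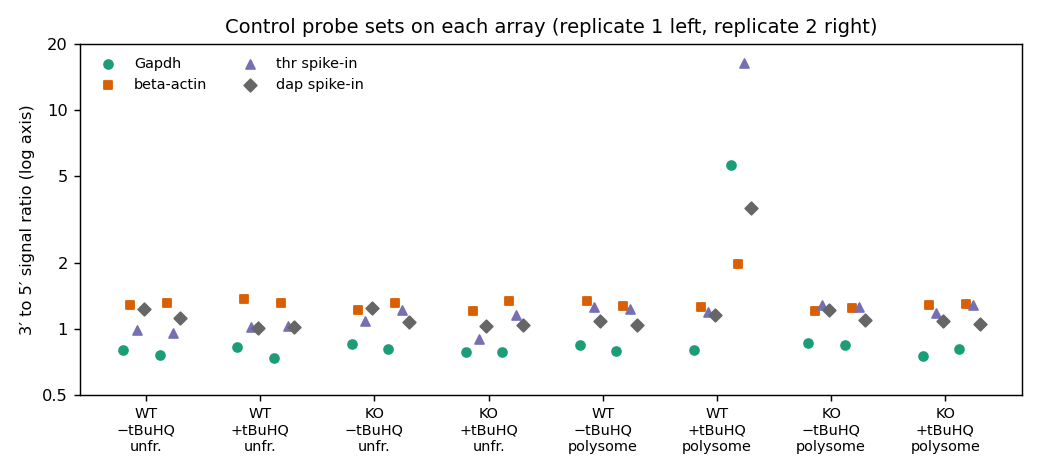
Ratio of 3′ to 5′ signal (log axis, no unit) of the Gapdh, beta-actin, thr spike-in and dap spike-in probe sets on each of the 16 arrays, with replicate 1 left and replicate 2 right in each group. The second wild-type tBuHQ polysome array reads 5.60 for Gapdh and 16.3 for thr, above all other arrays.

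The deleted gene itself was examined first. Eif2ak3, which encodes PERK, was 2.48-fold lower in knockout than in wild-type liver over both fractions and treatments, with a log2 difference of -1.31 ± 0.17 (SE, 8 against 8 arrays). limma gave an adjusted p of 0.0103 and an exact two-sided permutation test over 12870 splits gave p = 0.000311. Both tests took all arrays as independent, and the permutation also exchanged arrays across fractions and treatments. The fractions may share livers, in which case these p-values are too small. The Eif2ak3 probe set read 26.3 to 49.2 in the knockout arrays and 46.1 to 216 in the wild-type arrays, and 7 of the 8 knockout arrays lay below the lowest wild-type array. Over all genes, 19 differed between the genotypes in the limma test. Leaving out the second untreated wild-type unfractionated array (-1.27, adjusted p = 0.0626), the second untreated knockout unfractionated array (-1.29, 0.0568) or the first untreated knockout polysome array (-1.28, 0.0559) ended the call. Whether this probe set lies in the deleted part of the gene is not given in the sources used here, and other cells of the liver keep the gene.

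The first question was how tBuHQ, which empties the calcium store of the endoplasmic reticulum, changed the RNA of wild-type liver. The direction of every treatment difference here follows the sample titles. In the authors' deposited table of z scores, each of the 16 columns matched by value (largest residual 0.00368 on the log10 scale) an array whose title names the opposite treatment, with the same genotype and fraction, and 4 of them carried the other replicate number. By that table's column names every tBuHQ difference would turn its sign, and groups called untreated would be treated. The authors' deposited table gives Cyp2c37 a z ratio of 9.13 between its wild-type unfractionated columns and 8.95 between its wild-type polysome columns, in both cases the columns named without tBuHQ minus those named with it. Cyp2c37 was thus higher without tBuHQ by the column names and higher with it by the sample titles, and the ratios do not decide between them.

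In wild-type unfractionated RNA, Cyp2c37, a liver cytochrome P450, rose with tBuHQ (adjusted p = 0.000235), from signals of 31.8 and 9.34 on the untreated arrays to 1883 and 1708. Ddit3, which encodes the stress transcription factor CHOP, rose by 1.57 ± 0.33 on the log2 scale (SE, 2 against 2 arrays, adjusted p = 0.0214), from a mean signal of 101 to 342. Genes of the body clock rose as well, with Dbp at 3.14 ± 0.76, Nr1d1 at 2.05 ± 0.55 and Nr1d2 at 1.33 ± 0.25. The metal-binding metallothioneins Mt1 (2.21 ± 0.41) and Mt2 (2.10 ± 0.41), the interferon-induced chemokine Cxcl9 (2.26 ± 0.33) and the transcription factors Maff (from a mean of 11.5 to 98.8) and Myc (1.54 ± 0.29) rose too. The deepest decreases among named genes were those of the spectrin Sptbn1 (-2.72 ± 0.52), the endothelial phosphatase Ptprb (-2.67 ± 0.44), the kinase Hipk2 (-2.66 ± 0.50), the cytokine receptor Il6st (-2.59 ± 0.56), the desaturase-like Fads6 (-2.54 ± 0.62) and the RNA-binding Rc3h2 (-2.48 ± 0.30). In all, 49 genes rose and 469 fell of 12150. Absent spike-in probe sets read up to 15.1, and a difference from a group with an array under that level, as for Cyp2c37 and Maff without tBuHQ, has no exact size.

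Among 30 tested ISR targets of ATF4 and CHOP in wild-type unfractionated RNA, 2 rose, Ddit3 and the growth-arrest gene Gadd45a (1.77 ± 0.46), and 28 did not pass. Adjusted over the list alone, 2 were higher and 3 lower, and camera gave an adjusted p of 0.0686. Asns, the asparagine synthetase, stood at 1.24 ± 0.47 (adjusted p = 0.145), Atf4 at 0.70 ± 0.26 (0.137), Ppp1r15a at 0.36 ± 0.49 and Trib3 at 0.32 ± 0.33. Of 10 mRNAs with upstream reading frames that resist eIF2 phosphorylation, 1 rose (Ddit3), with 3 higher and 1 lower adjusted over the list alone. Of 21 endoplasmic reticulum chaperones and ATF6 targets 1 rose, Creld2 (1.87 ± 0.46), with 2 higher and 1 lower adjusted over the list alone. The chaperone Hspa5 stood at 0.38 ± 0.25, Herpud1 at 0.92 ± 0.31 (adjusted p = 0.109) and Xbp1 at 0.33 ± 0.31. Of 31 XBP1 targets and secretory genes the co-chaperone Dnajb9 rose (1.15 ± 0.30) and Edem3, of protein degradation, fell (-1.45 ± 0.31), with 3 higher and 1 lower adjusted over the list alone. Of 6 RIDD substrates, mRNAs that IRE1 can cleave, Pdgfrb (to a mean of 14.8) and Tapbp (-1.33 ± 0.29) fell, and 4 were lower adjusted over the list alone. None of 19 aminoacyl-tRNA synthetases passed, nor any adjusted over the list alone.

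Some genes of lipid synthesis were among those that fell with tBuHQ in wild-type unfractionated RNA. Of 15 lipogenic SREBP1 targets 4 fell, Gpam (-2.09 ± 0.36), Acacb (-2.09 ± 0.42), Fasn (-2.07 ± 0.34) and Acly (-1.38 ± 0.24), and 9 were lower adjusted over the list alone, with a list median of -0.98 and an adjusted p of 0.469 with an estimated correlation. Of 20 cholesterol synthesis genes 3 fell, Lss (-1.88 ± 0.29), Dhcr7 (-1.56 ± 0.39) and Hsd17b7 (-1.16 ± 0.29), and 4 were lower adjusted over the list alone, with a median of -0.38 and an adjusted p of 0.469 with an estimated correlation. Among markers of other liver cells, those that fell were 4 of 14 stellate cell markers (Reln -2.34 ± 0.41, Pdgfrb, Lrat -1.37 ± 0.30 and Rgs5 -1.18 ± 0.25) and 2 of 16 sinusoidal endothelial markers (Ptprb and Eng, -1.31 ± 0.35). Adjusted over each list alone 5 were lower in either, the medians were -0.47 and -0.65, and the adjusted p was 0.469 for either with an estimated correlation. Of 16 macrophage markers 1 fell, Csf1r (-1.84 ± 0.41), as it did adjusted over the list alone. Of 14 clock genes 3 rose and 2 fell, Clock (-1.56 ± 0.30) and Nfil3 (-1.11 ± 0.27), with 3 higher and 3 lower adjusted over the list alone.

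Camera called 16 lists in this comparison, 11 higher and 5 lower, and none with an estimated correlation, where their adjusted p ranged from 0.469 to 0.604. Medians were 0.53 for 73 oxidative phosphorylation genes, 0.44 for 44 ribosomal proteins, 0.40 for 38 proteasome genes and 0.23 for 15 other mRNAs with a 5' terminal oligopyrimidine tract. Of these lists, 1 member, Uqcrb (0.58 ± 0.15), passed over all genes and 0 adjusted over each list alone, so the call rests on camera. Camera also placed higher the immediate early genes (median 0.21, 2 of 33 risen, 6 adjusted over the list alone), heat shock genes (0.29, Hspa8 risen by 0.88 ± 0.23 among 16, 3 adjusted over the list alone) and inflammatory genes (0.44, with Icam1 fallen to a mean of 14.6 among 28, and also adjusted over the list alone). The XBP1 list (0.24) and pancreatic markers (2.20, 0 of 6 passed) were placed higher too. Cpa1 and Prss2 read under the absent spike-in level of 15.1 on both untreated wild-type unfractionated arrays, and Ctrb1 did on the second. Pancreatic medians here and below thus give a direction and no exact size. Plasma proteins (0.21, Apoc3 risen by 0.63 ± 0.15 and Itih1 fallen, -1.08 ± 0.24, among 33, with 8 higher and 2 lower adjusted over the list alone) and P450 enzymes (0.17, Cyp2c37 among 26, 2 adjusted over the list alone) were also placed higher. Quantile normalization turned the medians of plasma proteins and P450 enzymes to -0.11 and -0.0947 over all arrays and to -0.10 and -0.0923 within each fraction. Camera then called plasma proteins lower (adjusted p = 0.0188 over all arrays and 0.0170 within each fraction) and did not call P450 enzymes (0.711 and 0.698). Both calls ended without the second tBuHQ array (medians 0.04 and 0.06).

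No list call was made for gluconeogenesis and fasting genes (1 of 16, Ppara, -1.57 ± 0.34), hypoxia genes (of 15, Pdk1 at -1.08 ± 0.24 and Pfkfb3 at 1.10 ± 0.28 passed), apoptosis and p53 targets (1 of 17, Bid, -1.17 ± 0.25) or clock genes. The first 3 of these lists had the same counts adjusted over each list alone. NRF2 targets (20 tested), male-biased and Y-linked genes (10) and female-biased genes and Xist (6) had no called member either way. The median of the clock genes was -0.13 and their mean 0.03, with a test direction of lower. For NRF2 targets, apoptosis targets, male-biased and female-biased genes the median (-0.04, -0.01, 0.16 and -0.05) and mean (0.04, 0.06, -0.01 and 0.10) differed in sign too. The lists too small for camera had no member called over all genes: 3 cholangiocyte, 2 lymphocyte, 4 neutrophil and 4 erythroid markers, of which 1 lymphocyte marker was higher adjusted over the list alone. Eif2ak3 stood at 0.30 ± 0.35 and Alb, albumin, at 0.51 ± 0.16 (adjusted p = 0.0787).

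These calls rested on all 4 arrays of the comparison. Without the first or second untreated array 1 gene was called, without the first tBuHQ array 2 and without the second 35. Quantile normalization within each fraction gave 52 higher and 215 lower genes, and both untreated arrays belong to the 3 unfractionated arrays that stood apart from the other 5.

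**Figure D2:**
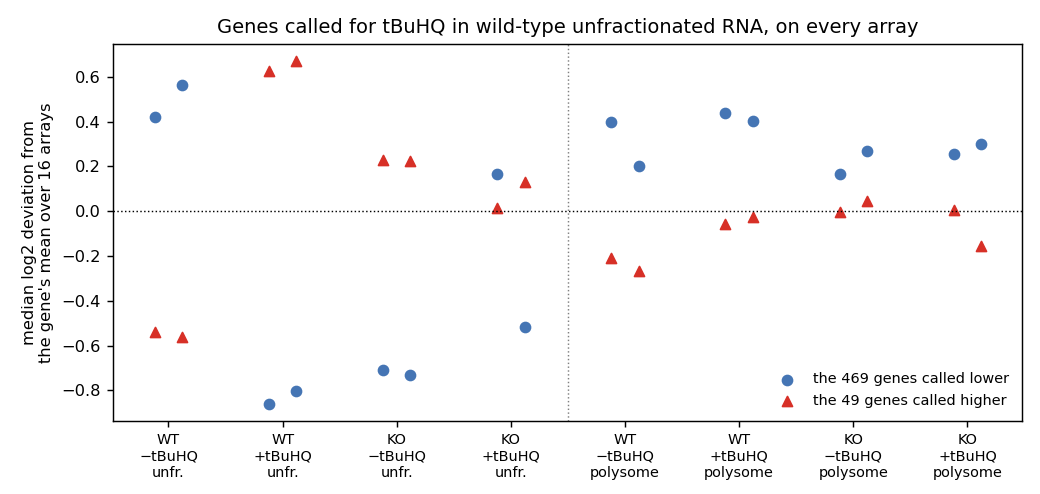
Median over genes of the log2 deviation from each gene's mean over the 16 arrays (vertical axis, log2), for the 469 genes lower (circles) and the 49 genes higher (triangles) with tBuHQ in wild-type unfractionated RNA, with a point per array. In knockout tBuHQ unfractionated RNA the medians of the lower genes are 0.17 on the first array and -0.52 on the second.

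The same treatment was then examined in livers without Perk, and the difference between genotypes was tested. In knockout unfractionated RNA limma called 0 genes at an adjusted p under 0.05, with 1014 at an unadjusted p under 0.05. Ddit3 stood at -0.64 ± 0.33, Herpud1 at -0.59 ± 0.31, Asns at -0.26 ± 0.47, Xbp1 at 0.27 ± 0.31 and Hspa5 at 0.02 ± 0.25 (2 against 2 arrays). Atf4 (-0.03 ± 0.26), Ppp1r15a (-0.17 ± 0.49), Trib3 (0.01 ± 0.33), Eif2ak3 (-0.08 ± 0.35) and Alb (0.06 ± 0.16) did not pass either. Camera called 12 lists, with an adjusted p of 0.242 to 0.553 with an estimated correlation. It placed P450 enzymes (median 0.47), plasma proteins (0.33), endoplasmic reticulum chaperones (0.56), stellate cell markers (0.67), endothelial markers (0.66), RIDD substrates (0.73), lipogenic genes (0.46) and gluconeogenesis genes (0.25) higher. It placed oxidative phosphorylation (-0.24), proteasome (-0.24), ribosomal protein (-0.19) and pancreatic genes (-1.78) lower. Adjusted over the list alone 2 P450 enzymes, 5 stellate markers, 3 RIDD substrates, 4 lipogenic genes and 1 gluconeogenesis gene were higher. Without the second knockout tBuHQ array 90 genes were called, and without the first the ribosomal protein median turned to 0.0477.

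The effect of tBuHQ differed between genotypes for 645 genes in unfractionated RNA, 594 with a positive and 51 with a negative difference. The difference is the knockout change minus the wild-type change, so its sign does not say which change was larger. For Ddit3 it was -2.20 ± 0.46 on the log2 scale (SE, adjusted p = 0.0157), and it was negative too for Cyp2c37 (adjusted p = 0.00715), the clock genes Dbp (-5.73 ± 1.08) and Nr1d2 (-1.64 ± 0.35), and the heat shock genes Hsph1 (-1.66 ± 0.42) and Dnaja1 (-1.29 ± 0.35). Herpud1 at -1.51 ± 0.44 (adjusted p = 0.0593) and Asns at -1.50 ± 0.66 (0.199) did not pass. Atf4 (-0.73 ± 0.37), Hspa5 (-0.36 ± 0.35), Ppp1r15a (-0.53 ± 0.69), Trib3 (-0.31 ± 0.47), Xbp1 (-0.06 ± 0.44), Eif2ak3 (-0.38 ± 0.49) and Alb (-0.45 ± 0.22) did not either. Sycn, a pancreatic granule protein, Ubqlnl, Tiam2 and Slc7a13 passed with a negative and Eppk1 with a positive difference, but at least 1 of their 4 groups lay under the absent spike-in level of 15.1, so the size of theirs was not measured. Their lowest group means were 5.47, 3.51, 12.7, 3.23 and 4.34. The same holds for Cyp2c37, with an array at 9.34 in untreated wild-type liver. Positive differences were those of Hipk2 (4.23 ± 0.70), Sptbn1 (4.07 ± 0.74), Il6st (4.07 ± 0.79), the phosphatase Ptprf (3.69 ± 0.54) and Fads6 (3.66 ± 0.88). Per array, Ptprf followed the split among the unfractionated arrays, with 970, 1028 and 987 on the 3 that stood apart and 187 to 296 on the other 5. Its knockout tBuHQ arrays read 987 and 296, against 198 and 201 without tBuHQ. Ddit3 read 95.4, 107 and 144 on those 3 arrays and 214 to 432 on the other 5.

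Camera called 10 lists, with an adjusted p of 0.298 to 0.608 with an estimated correlation. The difference was positive for 7 of 15 lipogenic genes, among them Gpam (3.21 ± 0.50), Acacb (3.06 ± 0.59), Fasn (2.53 ± 0.48) and the desaturase Scd1 (2.52 ± 0.54), with 8 adjusted over the list alone and a median of 1.47. Gpam stood at -2.09 in wild-type and 1.12 in knockout liver, and Fasn at -2.07 and 0.46. The difference was also positive for 5 of 14 stellate cell markers (Reln 3.38 ± 0.58, Pdgfrb, Lrat 2.25 ± 0.43, Col3a1 1.86 ± 0.47 and Rgs5 1.72 ± 0.35), 3 of 16 endothelial markers (Ptprb 3.63 ± 0.62, Kdr 1.87 ± 0.45 and Stab1 1.85 ± 0.50), and 3 of 6 RIDD substrates (Pdgfrb, with a lowest group mean of 10.6, Tapbp 2.28 ± 0.41 and Sparc 2.04 ± 0.49). Adjusted over each list alone these were 7, 7 and 4, and the medians 1.15, 1.13 and 1.59. Of 20 cholesterol synthesis genes Dhcr7 (2.53 ± 0.56) and Lss (1.86 ± 0.41) passed, 5 adjusted over the list alone, with a median of 0.60. Medians were -0.72 for oxidative phosphorylation, -0.70 for proteasome, -0.61 for ribosomal protein and -0.35 for heat shock genes, and -4.23 for pancreatic markers. No member of these lists passed but Hsph1 and Dnaja1, which were 2 of 16 heat shock genes and 3 adjusted over the list alone, and 1 pancreatic marker was lower adjusted over the list alone. Of 14 clock genes Clock was higher (2.03 ± 0.43) and Dbp and Nr1d2 lower, with 2 higher and 3 lower adjusted over the list alone. Of 30 ISR targets Ddit3 was lower and Vldlr, a lipoprotein receptor, higher (2.34 ± 0.55), with 2 higher and 2 lower adjusted over the list alone and no list call.

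Leaving out 1 array moved the count of 645 genes to 240 without the first and 0 without the second untreated wild-type array, and to 159 without the first and 371 without the second wild-type tBuHQ array. It moved to 164 and 216 without the first and second untreated knockout array, and to 94 and 1172 without the first and second knockout tBuHQ array, of which the first stood with the untreated wild-type arrays.

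**Figure D3:**
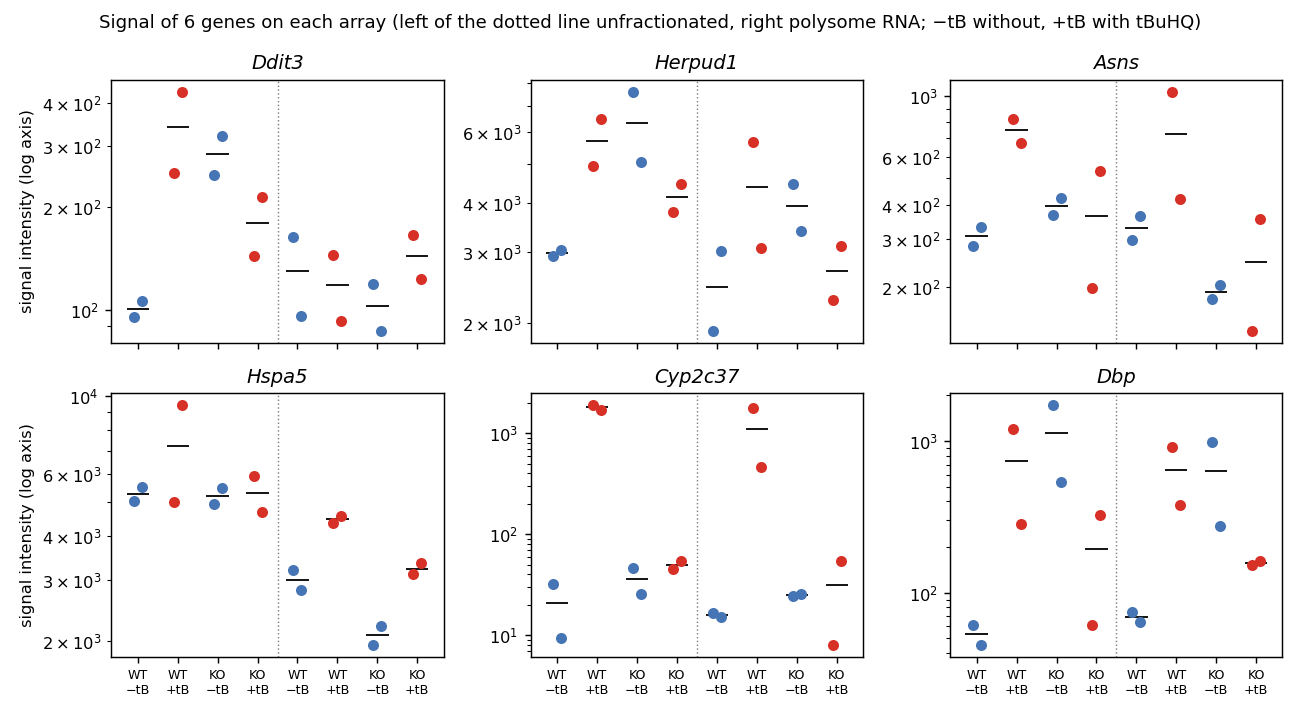
Signal intensity on each array (log axis, arbitrary units scaled to a trimmed mean of 150) of Ddit3, Herpud1, Asns, Hspa5, Cyp2c37 and Dbp, in 8 groups of 2 arrays, with a line at the group mean and red points for tBuHQ. Cyp2c37 has a mean of 1796 in wild-type tBuHQ unfractionated RNA and of 20.6 without tBuHQ.

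Polysome RNA holds the mRNA being translated, and the same questions were put to it. In wild-type polysome RNA 2 genes rose with tBuHQ, the clock repressor Nr1d2 by 1.90 ± 0.25 on the log2 scale (SE, 2 against 2 arrays, adjusted p = 0.0105) and Cyp2c37 (0.00193) from signals of 16.6 and 15.2, near the absent spike-in level, to 1754 and 464, and 0 fell. A dimmer probe set of Nr1d2, not the one tested, read 61.2 and 57.1 without and 283 and 5.80 with tBuHQ there. The reading of 5.80 came from the array with the raised 3' to 5' ratios. Asns stood at 0.98 ± 0.47, Eif2ak3 at 0.97 ± 0.35, Herpud1 at 0.80 ± 0.31, Hspa5 at 0.57 ± 0.25, Ddit3 at -0.10 ± 0.33 and Atf4 at -0.27 ± 0.26, with adjusted p from 0.417 for Eif2ak3 to 0.942 for Ddit3. Trib3 (0.42 ± 0.33), Alb (0.07 ± 0.16), Xbp1 (-0.05 ± 0.31) and Ppp1r15a (-0.51 ± 0.49) did not pass. In knockout polysome RNA limma called 0 genes, with 701 at an unadjusted p under 0.05. Hspa5 stood at 0.63 ± 0.25 there, Ppp1r15a at 0.46 ± 0.49, Ddit3 at 0.43 ± 0.33, Xbp1 at 0.42 ± 0.31, Herpud1 at -0.54 ± 0.31 and Trib3 at -0.66 ± 0.33. Asns (0.20 ± 0.47), Atf4 (0.18 ± 0.26), Eif2ak3 (0.12 ± 0.35) and Alb (-0.15 ± 0.16) did not pass.

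Camera called 8 lists in wild-type polysome RNA, with an adjusted p of 0.637 with an estimated correlation. Gene lists in wild-type polysome RNA were placed higher for P450 enzymes (median 0.45, Cyp2c37 the 1 member risen of 26, 7 adjusted over the list alone), endoplasmic reticulum chaperones (0.43, 0 of 21, 1 adjusted over the list alone), plasma proteins (0.35) and RIDD substrates (0.65, 3 of 6 adjusted over the list alone). They were placed lower for ribosomal proteins (-0.26), oxidative phosphorylation (-0.26), cholesterol synthesis (-0.21, 2 of 20 adjusted over the list alone) and lipogenesis (-0.37). In knockout polysome RNA the gluconeogenesis and fasting list was placed higher (median 0.45, 0 of 16 passed, 2 adjusted over the list alone), with an adjusted p of 0.0482 with an estimated correlation. Another 11 lists were called, with an adjusted p of 0.377 to 0.539 with an estimated correlation. Placed higher as well were P450 enzymes (0.54, 8 adjusted over the list alone), chaperones (0.42), plasma proteins (0.31, 6 adjusted over the list alone), aminoacyl-tRNA synthetases (0.27), immediate early genes (0.30), RIDD substrates (0.38), stellate cell markers (0.48) and male-biased genes (0.43, 3 adjusted over the list alone). Ribosomal proteins (-0.29), oxidative phosphorylation (-0.28) and pancreatic markers (-1.57) were placed lower.

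For the difference between genotypes in this effect in polysome RNA, limma called 0 genes, with 618 at an unadjusted p under 0.05. Herpud1 differed by -1.34 ± 0.44, Trib3 by -1.08 ± 0.47, Ppp1r15a by 0.98 ± 0.69, Eif2ak3 by -0.85 ± 0.49, Asns by -0.77 ± 0.66, Ddit3 by 0.53 ± 0.46, Xbp1 by 0.47 ± 0.44, Atf4 by 0.45 ± 0.37, Alb by -0.22 ± 0.22 and Hspa5 by 0.05 ± 0.35. Camera placed lipogenesis (0.43), cholesterol synthesis (0.46), gluconeogenesis (0.37), immediate early (0.44) and stellate genes (0.33) higher and pancreatic markers (-2.72) lower. The 6 calls had an adjusted p of 0.241 to 0.889 with an estimated correlation, and no member passed, nor did any adjusted over the list alone. The second wild-type tBuHQ array of this fraction is the array with the raised 3' to 5' ratios. Without it 147 genes were called in the wild-type and 1 in the difference between genotypes, and without the first wild-type tBuHQ array 286 and 154. Without the first or second untreated wild-type array 0 and 4 were called in the wild-type, and without the second knockout tBuHQ array 1 in the difference.

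**Figure D4:**
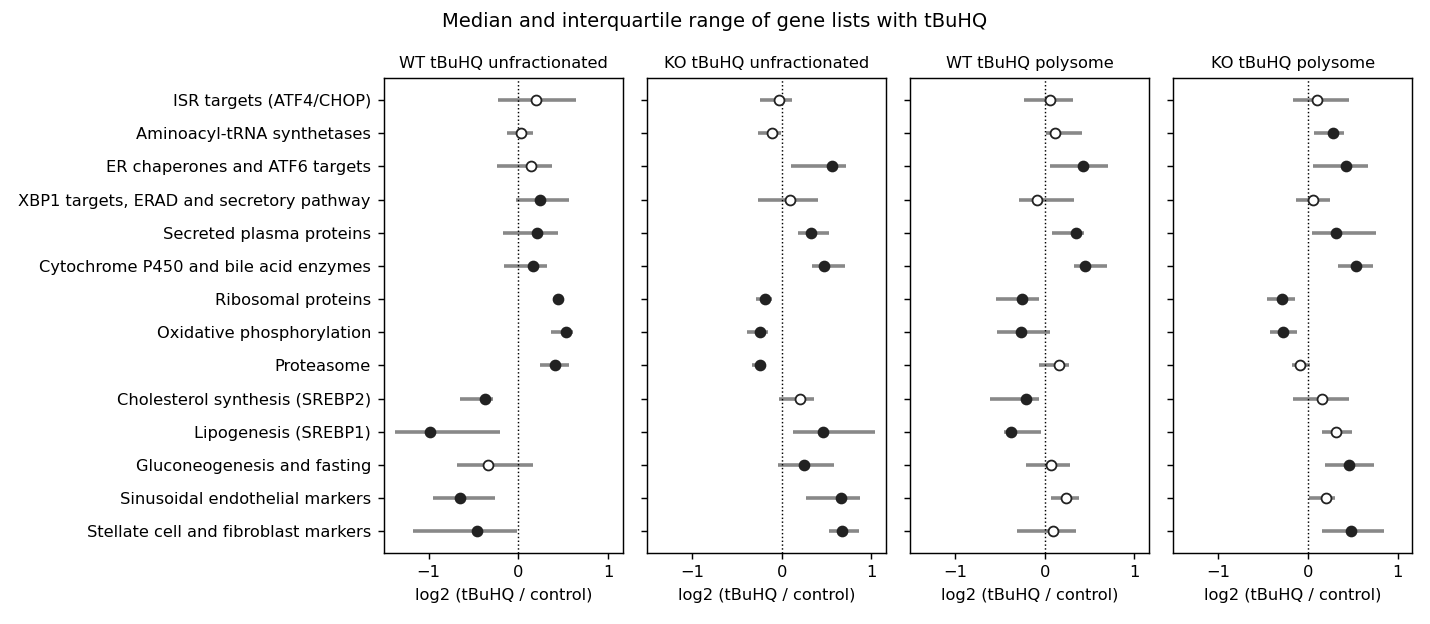
Median (point) and interquartile range (line) over members of the log2 difference with tBuHQ (horizontal axis) for 14 gene lists in 4 comparisons, with filled points for an adjusted p under 0.05 in camera with the preset correlation. Lipogenesis lies at -0.98 in wild-type and 0.46 in knockout unfractionated RNA, and wild-type plasma protein and P450 medians there turn negative under quantile normalization. Camera then calls plasma proteins lower and does not call P450 enzymes.

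The shift of mRNA into or out of polysomes with tBuHQ was measured as the change in polysome RNA minus that in unfractionated RNA. Every array of both fractions was scaled to the same trimmed mean, so a shift common to all mRNAs cannot be seen. This difference is thus relative to the other mRNAs. In wild-type liver this difference was positive for 12 genes, among them Rc3h2 (2.72 ± 0.43), Ago2, the lymphatic receptor Flt4 (2.59 ± 0.43), the collagen Col14a1 (2.48 ± 0.43), Adgrf5 (2.37 ± 0.39) and Larp4 (2.15 ± 0.38), and negative for 1, Sys1 (-2.10 ± 0.37), each with an adjusted p of 0.0455. The change lay mostly in unfractionated RNA for Rc3h2, whose mean signal went from 330 to 46.1 there and from 401 to 476 in polysome RNA, and for Ago2, from 123 to 12.7, under the absent spike-in level, and from 114 to 156. Ddit3 stood at -1.67 ± 0.46 (adjusted p = 0.0936) and Atf4 at -0.97 ± 0.37 (0.187). Ppp1r15a (-0.87 ± 0.69), Alb (-0.44 ± 0.22), Xbp1 (-0.38 ± 0.44), Asns (-0.26 ± 0.66), Herpud1 (-0.12 ± 0.44), Trib3 (0.10 ± 0.47), Hspa5 (0.20 ± 0.35) and Eif2ak3 (0.67 ± 0.49) did not pass. Camera called 6 lists, with an adjusted p of 0.436 to 0.759 with an estimated correlation. It placed oxidative phosphorylation (-0.84), ribosomal protein (-0.61), proteasome (-0.24) and immediate early genes (-0.27) lower, and RIDD substrates (1.31) and endothelial markers (0.81) higher. No member passed over all genes, and 5 RIDD substrates and 3 endothelial markers were higher and 1 oxidative phosphorylation gene lower adjusted over the list alone. The count of 13 genes depended on the processing. It was 126 with the pool as a random block, 37 with the 60th percentile filter and 29 with an offset of 64, each keeping all 13. It was 18 with median centring, 12 with only the arrays of the comparison and 2 with no filter, which kept 12, 5 and 1 of the 13. With quantile normalization, an offset of 1, all probe sets, eBayes without a trend, the replicate block, the span trend removed or the authors' z scores 0 of the 13 calls were left, and without the first or second wild-type tBuHQ polysome array 372 and 540 genes were called. Without any other array of the comparison 0 were called.

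In knockout liver limma called 0 genes for this shift, with 361 at an unadjusted p under 0.05. Ddit3 stood at 1.06 ± 0.46, Ppp1r15a at 0.64 ± 0.69, Hspa5 at 0.61 ± 0.35, Asns at 0.47 ± 0.66, Atf4 at 0.21 ± 0.37, Eif2ak3 at 0.20 ± 0.49, Xbp1 at 0.15 ± 0.44, Herpud1 at 0.05 ± 0.44, Alb at -0.21 ± 0.22 and Trib3 at -0.67 ± 0.47. Aminoacyl-tRNA synthetases (0.39), proteasome (0.18) and heat shock genes (0.27) were placed higher and endothelial markers (-0.39) lower, with no member past any adjustment and an adjusted p of 0.559 to 0.981 with an estimated correlation. For the difference between genotypes in this shift limma called 0 genes, with 1532 at an unadjusted p under 0.05. Ddit3 had 2.73 ± 0.65 there (adjusted p = 0.111), Ppp1r15a 1.51 ± 0.97, Atf4 1.18 ± 0.52, Asns 0.73 ± 0.93, Xbp1 0.53 ± 0.63, Hspa5 0.41 ± 0.50, Alb 0.23 ± 0.31, Herpud1 0.17 ± 0.62, Eif2ak3 -0.47 ± 0.69 and Trib3 -0.78 ± 0.66. Camera called 8 lists, with an adjusted p of 0.438 to 0.689 with an estimated correlation. Oxidative phosphorylation (0.74), ribosomal protein (0.55), proteasome (0.44) and immediate early genes (0.49) were placed higher, and RIDD substrates (-1.78), endothelial (-1.28), stellate (-0.71) and lipogenic genes (-0.85) lower. Adjusted over each list alone 4, 1, 3 and 1 of these last lists passed. Without the second knockout tBuHQ unfractionated array 395 genes were called, without the first wild-type tBuHQ polysome array 142 and without any other array 0.

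Livers with and without Perk were also compared in the absence of tBuHQ. In unfractionated RNA 87 genes were higher and 762 lower in the knockout, with the untreated arrays taken by the sample titles. With the authors' z scores by their column names, which take the arrays titled tBuHQ as untreated, this comparison called 0 genes. Of 14 clock genes 3 were higher, with Dbp at 3.84 ± 0.76 on the log2 scale (SE, 2 against 2 arrays, adjusted p = 0.0108), Nr1d1 at 2.86 ± 0.55 and Nr1d2 at 1.59 ± 0.25, and Clock was lower (-1.49 ± 0.30), with the same counts adjusted over the list alone and no list call. Rgs16 (2.47 ± 0.50), Mt1 (1.97 ± 0.41), Maff and the glycogen-targeting Ppp1r3g were higher as well. Il6st (-3.25 ± 0.56), Sptbn1 (-2.79 ± 0.52), Fads6 (-2.64 ± 0.62), Zhx3, Itih5 and Hectd4 were lower. For Maff, Ppp1r3g, Zhx3, Itih5 and Hectd4 at least 1 array of the lower group read under the absent spike-in level of 15.1, so that the size of the difference was not measured. The means of those groups were 11.5, 19.2, 33.9, 18.7 and 3.74. Eif2ak3 stood at -1.08 ± 0.35 (adjusted p = 0.0742).

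Of 30 ISR targets 3 were higher in untreated knockout unfractionated RNA, Gadd45b (1.85 ± 0.53), Gadd45a (1.68 ± 0.46) and Ddit3 (1.35 ± 0.33, adjusted p = 0.0248), with 3 higher and 2 lower adjusted over the list alone. Trib3 (0.57 ± 0.33), Ppp1r15a (0.56 ± 0.49), Asns (0.35 ± 0.47) and Atf4 (0.14 ± 0.26) did not pass, nor did Herpud1 (1.05 ± 0.31, 0.0557), Alb (0.16 ± 0.16), Hspa5 (-0.02 ± 0.25) or Xbp1 (-0.42 ± 0.31). Of 16 heat shock genes 4 were higher, such as Hspa1b (1.27 ± 0.27), and of 33 immediate early genes 3 (Maff, Klf10 and Zfp36, 0.65 ± 0.19), with 4 and 5 adjusted over each list alone. Of 21 endoplasmic reticulum chaperones 5 were lower, Sel1l (-1.46 ± 0.39), Hspa13 (-1.14 ± 0.29), Calr (-1.13 ± 0.26), Canx (-1.12 ± 0.29) and P4hb (-1.07 ± 0.27), with 1 higher and 11 lower adjusted over the list alone. Of 31 XBP1 and secretory genes 5 were lower, Edem3 (-1.70 ± 0.31), the translocon subunit Sec61a1 (-1.32 ± 0.32), Ssr1 (-1.27 ± 0.28), Spcs3 (-1.10 ± 0.28) and Ssr3 (-0.93 ± 0.22), with 6 adjusted over the list alone and no list call.

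Lower in untreated knockout unfractionated RNA were also 4 of 15 lipogenic genes (Gpam -2.15 ± 0.36, Acacb -1.86 ± 0.42, Elovl6 -1.79 ± 0.35 and Srebf1 -1.33 ± 0.34) and 5 of 20 cholesterol synthesis genes (Dhcr7 -1.98 ± 0.39, Msmo1 -1.43 ± 0.36, Cyp51 -1.35 ± 0.24, Hsd17b7 -1.30 ± 0.29 and Lss -1.06 ± 0.29), with 6 and 8 adjusted over each list alone. So were 6 of 14 stellate markers (Reln -2.13 ± 0.41, Lrat -1.74 ± 0.30), 4 of 16 endothelial markers (Ptprb -2.09 ± 0.44, Kdr -1.31 ± 0.32), 4 of 6 RIDD substrates (Sparc -1.96 ± 0.35, Tapbp -1.62 ± 0.29) and 4 of 33 plasma proteins (Apob -2.51 ± 0.50). The counts were 8, 9, 4 and 5 adjusted over each list alone. These 6 lists were called by camera, with an adjusted p of 0.253 to 0.637 with an estimated correlation. Of 15 hypoxia genes 3 were lower, Slc2a1 (-1.14 ± 0.29), Vegfa (-1.08 ± 0.30) and Pdk1 (-0.87 ± 0.24), with 2 higher and 4 lower adjusted over the list alone. Camera called 16 lists, 7 higher and 9 lower, with medians of 0.50 for oxidative phosphorylation, 0.56 for proteasome, 0.42 for ribosomal protein and 1.73 for pancreatic genes among the higher. Medians among the lower were -1.29 for RIDD substrates, -0.94 for stellate markers, -0.87 for chaperones, -0.70 for lipogenesis, -0.50 for cholesterol synthesis, -0.51 for male-biased genes (2 of 10 lower, 4 adjusted over the list alone), -0.39 for P450 enzymes (1 of 26, Cyp4v3, -1.35 ± 0.28, as adjusted over the list alone) and -0.27 for plasma proteins. Over the 16 calls too the adjusted p was 0.253 to 0.637 with an estimated correlation. The count of 849 genes went to 0 without either untreated wild-type array, both of which stood apart from 5 of the other unfractionated arrays, and to 1 and 9 without the first and second untreated knockout array.

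In polysome RNA of the same untreated groups 1 gene was higher in the knockout, Nr1d2 (1.97 ± 0.25, adjusted p = 0.0129), and 0 were lower. It was not called with median centring, with the authors' z scores by their column names or without any 1 of the 4 arrays, and quantile normalization over all arrays gave 1 higher and 1 lower gene. Eif2ak3 stood at -0.93 ± 0.35 (0.606), Asns at -0.73 ± 0.47, Herpud1 at 0.69 ± 0.31, Trib3 at 0.56 ± 0.33, Hspa5 at -0.52 ± 0.25, Atf4 at -0.40 ± 0.26, Ppp1r15a at -0.36 ± 0.49, Alb at 0.30 ± 0.16, Ddit3 at -0.26 ± 0.33 and Xbp1 at -0.10 ± 0.31. Aminoacyl-tRNA synthetases (median -0.39, 3 of 19 lower adjusted over the list alone), male-biased genes (-0.51, 3 of 10), P450 enzymes (-0.32), cholesterol synthesis (-0.29, 2 of 20), lipogenesis (-0.43) and gluconeogenesis genes (-0.26) were placed lower. Oxidative phosphorylation (0.26) and pancreatic markers (1.25) were placed higher. The 8 calls had an adjusted p of 0.213 to 0.776 with an estimated correlation.

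Finally polysome RNA was compared with unfractionated RNA of untreated liver, which ranks mRNAs by their share on polysomes. In wild-type liver 72 genes were lower in polysome RNA and 1 higher, Cntd1 (1.20 ± 0.24). The lowest were the mitochondrially translated ND5 (-4.56 ± 0.66, adjusted p = 0.00516), the nuclear noncoding RNA Neat1 (-2.77 ± 0.39), the proteoglycan Bgn (-2.48 ± 0.29), the snoRNA host genes Snhg6 (-2.43 ± 0.33) and Snhg8 (-2.28 ± 0.39), and Apob (-2.36 ± 0.50). Of 44 ribosomal proteins 6 were lower (Rps19 -1.60 ± 0.28, Rplp0 -1.45 ± 0.21, Rps3a1 -1.11 ± 0.21, Rps6 -1.11 ± 0.24, Rps2 -1.08 ± 0.17 and Rpl10a -0.97 ± 0.20), and 20 adjusted over the list alone. Of 16 macrophage markers 4 were lower, such as Csf1r (-2.04 ± 0.41) and C1qb (-1.45 ± 0.26), 14 adjusted over the list alone, with a median of -1.35 and an adjusted p of 0.0418 with an estimated correlation. RIDD substrates, with Sparc (-1.91 ± 0.35) lower of 6 and 6 adjusted over the list alone, had a median of -1.11 and the same adjusted p with an estimated correlation.

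Other lists were placed lower in wild-type polysomes, with an adjusted p of up to 0.489 with an estimated correlation. They were stellate markers (3 of 14, such as Reln -2.23 ± 0.41 and Ecm1 -2.08 ± 0.28), endothelial markers (1 of 16, Fcgr2b, -1.99 ± 0.30), plasma proteins (2 of 33), other terminal oligopyrimidine mRNAs (1 of 15, Eef1b2, -1.51 ± 0.22), chaperones (0 of 21), P450 enzymes (0 of 26), inflammatory genes (0 of 28), XBP1 targets, cholesterol synthesis and male-biased genes. Adjusted over each list alone 11, 11, 24, 9, 11, 16, 7, 2, 2 and 2 of these were lower. Placed higher were oxidative phosphorylation (median 0.25) and mRNAs with upstream reading frames (0.26, 2 of 10 adjusted over the list alone). Of the genes always named, Atf4 (0.80 ± 0.26, adjusted p = 0.175) and Hspa5 (-0.82 ± 0.25, 0.149) were nearest to the threshold. Ppp1r15a (0.32 ± 0.49), Ddit3 (0.28 ± 0.33), Trib3 (0.20 ± 0.33), Asns (0.09 ± 0.47), Alb (-0.20 ± 0.16), Herpud1 (-0.32 ± 0.31), Eif2ak3 (-0.44 ± 0.35) and Xbp1 (-0.46 ± 0.31) did not pass. The count of 73 genes went to 0 and 8 without the first and second unfractionated array, and to 14 without either polysome array.

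In knockout liver 711 genes were higher and 433 lower in polysome RNA than in unfractionated RNA, against 1 and 72 in wild-type liver. With the authors' z scores by their column names, which take the arrays titled tBuHQ as untreated, 37 were higher and 65 lower in knockout liver and 1211 and 645 in wild-type liver, so which genotype has more called genes depends on the treatment labels. The noncoding Snhg8 (-4.06 ± 0.39), Snhg6 (-4.03 ± 0.33, adjusted p = 4.12e-05), Neat1 (-3.75 ± 0.39) and Gas5 (-3.74 ± 0.56), and Rpl41 (-3.03 ± 0.71) and ND5 (-2.71 ± 0.66) were lowest. Lpp (2.78 ± 0.43), Mfhas1 (2.47 ± 0.41), the repressor Zbtb20 (2.46 ± 0.38), Nfia (2.44 ± 0.41) and Wwc2 (2.44 ± 0.27) were among the highest, as was Zhx3, with an unfractionated array under the absent spike-in level. The mean signal of Lpp was 629 in wild-type and 117 in knockout unfractionated RNA, and 938 and 897 in polysome RNA, and that of Nfia was 708 and 176, and 986 and 1098. The untreated unfractionated arrays of the genotypes lie on different sides of the split among those arrays. Of 44 ribosomal proteins 24 were lower and of 15 other terminal oligopyrimidine mRNAs 11, such as Rps19 (-2.19 ± 0.28) and Eef1b2 (-2.09 ± 0.22), with 32 and 12 adjusted over each list alone and an adjusted p of 0.12 for either list with an estimated correlation. Of 10 mRNAs with upstream reading frames, the eIF2 phosphatase subunit Ppp1r15b (1.35 ± 0.33) and Ibtk (1.28 ± 0.24) were higher and Ddit3 lower (-1.34 ± 0.33, adjusted p = 0.0189), as they were adjusted over the list alone. Hspa5 was lower (-1.31 ± 0.25), while Asns (-0.98 ± 0.47), Herpud1 (-0.67 ± 0.31), Ppp1r15a (-0.60 ± 0.49), Eif2ak3 (-0.29 ± 0.35), Xbp1 (-0.14 ± 0.31), Alb (-0.06 ± 0.16), Trib3 (0.19 ± 0.33) and Atf4 (0.27 ± 0.26) did not pass.

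Further lists were placed lower in knockout polysomes, with an adjusted p of 0.12 to 0.536 with an estimated correlation. Of 19 aminoacyl-tRNA synthetases 6 were lower, such as Cars (-1.09 ± 0.25) and Tars (-1.06 ± 0.19), of 16 heat shock genes 5, such as Hspa4 (-1.34 ± 0.24) and Hspd1 (-0.78 ± 0.16), of 16 macrophage markers 6, such as Tyrobp (-2.64 ± 0.38), and of 28 inflammatory genes 4, such as Cxcl1 (-2.66 ± 0.43). So were 7 of 33 plasma proteins (Itih1 -1.23 ± 0.24), 5 of 26 P450 enzymes (Cyp3a25 -1.21 ± 0.22 and Cyp2f2 -0.65 ± 0.17 among them), 3 of 33 immediate early genes (Jun -1.46 ± 0.23), 3 of 10 male-biased genes (Cyp7b1 -1.16 ± 0.20) and 2 of 38 proteasome genes (Psma1 -0.95 ± 0.25). Adjusted over each list alone 7, 5, 9, 4, 12, 6, 8, 4 and 0 of these were lower. With the ribosomal protein and terminal oligopyrimidine lists these were 11 calls. The count of 1144 genes went to 210 and 236 without the first and second unfractionated array, and to 463 and 122 without the first and second polysome array.

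**Figure D5:**
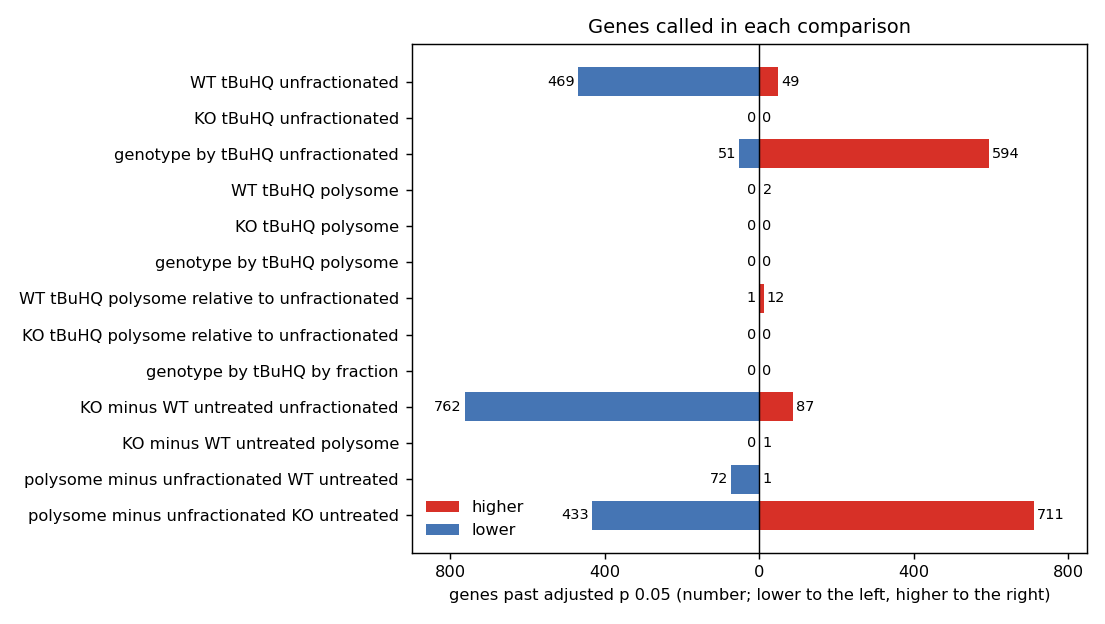
Number of genes past an adjusted p of 0.05 in limma for each of the 13 comparisons, with higher genes to the right and lower genes to the left of 0. By the sample titles 1144 genes are called between the fractions of untreated knockout liver and 849 between genotypes in untreated unfractionated RNA, against 102 and 0 with the authors' z scores by their column names.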

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

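The tests of a difference between RNA preparations, of polysome RNA, of spike-in ratios and of clock genes were chosen after the result was seen, and removing the trend on gene span was added after seeing the data with its bounds set before its result.

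The first pattern was the 518 genes called for tBuHQ in wild-type unfractionated RNA. The same wild-type arrays also enter the test of the 645 genes whose effect differed between genotypes. For the 469 genes called lower, polysome RNA argued against a change of transcript level that both fractions share. There they had a median change of -0.14 in the direction of the call, against 1.34 in unfractionated RNA, where they were selected. The 95% interval over genes (-0.19 to -0.11) does not measure the spread between arrays. Per array, their median deviation from the gene's mean was 0.40 and 0.20 in untreated wild-type polysome RNA. With tBuHQ it was 0.44 and 0.40, the second on the array with the raised 3' to 5' ratios. For the 49 genes called higher a change that both fractions share could not be told apart from other causes. Their median was 0.28 (interval over genes 0.03 to 0.44) against 1.19, and 32 of them rose in polysome RNA. A difference between RNA preparations not tied to treatment or genotype may account for part of the lower genes. Between the 2 knockout tBuHQ unfractionated arrays 93.8% of them differed in the direction of the call. The order of replicates is arbitrary in every group. Over all 518 genes the share in whichever direction was larger was 90.5% there and 51.4 to 74.9% in the other groups. The first of these knockout arrays had already been seen to stand with the untreated wild-type arrays. The share thus restates that split and is no separate test of it. For the genes called higher the share in the direction of the call was 59.2%, which leaves a difference between preparations open. A loss of signal that follows gene span could not be told apart from other causes, because 313 of the 518 genes (60.4%) were still called once each array's trend was removed, between the bounds set in advance. The median span was 61.0 kb for genes called lower, 7.45 kb for genes called higher and 22.4 kb for all. Across genes, the rank correlation of span with the deviation from the gene's mean was 0.11 and 0.18 on the untreated wild-type unfractionated arrays. It was 0.05 and -0.26 on the knockout tBuHQ, -0.30 and -0.23 on the wild-type tBuHQ and -0.32 and -0.29 on the untreated knockout arrays. These correlations went with the split among the unfractionated arrays. An effect of tBuHQ in wild-type liver that is confined to RNA outside polysomes stays open, since it was not tested apart from a difference between preparations. By the sample titles, though, the 469 genes were also low without tBuHQ in knockout unfractionated RNA. Their median deviation from the gene's mean was -0.71 and -0.73 there, against -0.86 and -0.80 on the wild-type tBuHQ arrays. It was 0.42 and 0.56 on the untreated wild-type and 0.17 and -0.52 on the knockout tBuHQ arrays.

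The second pattern was the second wild-type tBuHQ polysome array, whose Gapdh ratio of 3' to 5' signal of 5.60 lay outside the comparisons and far from the other 15 arrays. Degradation of the liver RNA before the spike-in RNA was added would leave the spike-in RNA intact, yet its thr ratio was 16.3, against 0.900 to 1.29 elsewhere. Short labelled cDNA from all RNA in that reaction may account for it, and could not be told apart from other faults of that array: 2 of 4 spike-in RNAs had over 2 times the highest ratio of the other arrays, all 4 lay above them, and the 3 RNAs added before hybridisation lay within their range. No biological explanation was tested.

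The third pattern was the clock genes that differed between arrays and between genotypes in the effect of tBuHQ (Dbp -5.73, Nr1d2 -1.64 and Clock 2.03). An effect of tBuHQ on them in both genotypes could not be excluded. The mean of 6 day-phase genes changed by 1.07 in wild-type and by -0.65 in knockout unfractionated RNA and by 1.26 and -0.35 in polysome RNA, but genes chosen for a genotype difference tend to give such values. In the knockout, leaving out 1 array gave -0.93 to -0.37 in unfractionated RNA, with -0.37 without the first tBuHQ array and -0.42 without the first untreated array, and -0.67 to -0.04 in polysome RNA, with -0.04 without the first and -0.67 without the second untreated array. Livers taken at different times of the day could not be told apart from an effect of genotype or treatment on the clock, which would give the same relations. Across the 8 unfractionated arrays the day-phase mean went against the mean of 4 night-phase genes with r = -0.909 (exact permutation p = 0.00394, adjusted over 3 relations 0.00592; rho = -0.857, p = 0.0107, adjusted 0.0107; r = -0.836 without the 2 farthest arrays). The 3 arrays with the highest night-phase means are those that stood apart in the first pattern, but polysome RNA gave r = -0.825 (exact permutation p = 0.0135, adjusted 0.0135; rho = -0.881, p = 0.00724, adjusted 0.0107; r = -0.884 without 2), and the day-phase mean of both fractions by number gave r = 0.938 (exact permutation p = 0.000273, adjusted 0.000818; rho = 0.976, p = 0.000397, adjusted 0.00119; r = 0.814 without 2). These sets hold the clock genes that had been called. Between the 2 arrays of a group, which share genotype and treatment, the means moved opposite ways in 7 of 8 groups (exact sign test p = 0.0703), and the fractions may share livers. A genotype effect, or an effect of tBuHQ that differs by genotype, stays open.

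Other genes stood out because the effect of tBuHQ in unfractionated RNA differed between genotypes in limma. The knockout change minus the wild-type change, on the log2 scale, was positive for Hipk2 (4.23), Eppk1 (4.08), Sptbn1 (4.07), Il6st (4.07), Ptprf (3.69), Fads6 (3.66), Ptprb (3.63), Reln (3.38), Gpam (3.21), Acacb (3.06), Pdgfrb (2.73), Fasn (2.53), Dhcr7 (2.53), Scd1 (2.52), Tapbp (2.28), Lrat (2.25), Sparc (2.04), Kdr (1.87), Lss (1.86), Col3a1 (1.86) and Stab1 (1.85). It was negative for Cyp2c37 (-5.35), Sycn (-2.89), Ubqlnl (-2.64), Tiam2 (-2.60), Slc7a13 (-2.58), Ddit3 (-2.20), Hsph1 (-1.66) and Dnaja1 (-1.29). For Cyp2c37, Eppk1, Sycn, Ubqlnl, Tiam2, Slc7a13 and Pdgfrb at least 1 array lay under the absent spike-in level of 15.1, so these values give a direction and no exact size. With camera's preset correlation 10 lists were called there, and 0 with an estimated correlation (adjusted p = 0.298 to 0.608). Their medians were 1.59 for RIDD substrates, 1.47 for lipogenesis, 1.15 for stellate cell markers, 1.13 for endothelial markers, 0.60 for cholesterol synthesis, -0.35 for heat shock genes, -0.61 for ribosomal proteins, -0.70 for the proteasome, -0.72 for oxidative phosphorylation and -4.23 for pancreatic markers, of which 5 of 6 were high on the first array alone of the wild-type tBuHQ and untreated knockout groups. The pancreatic median has no exact size either, since Cpa1 and Prss2 lay under the absent spike-in level on both untreated wild-type arrays.

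In polysome RNA the preset correlation called the genotype difference for the lists of cholesterol synthesis (0.46), immediate early genes (0.44), lipogenesis (0.43), gluconeogenesis (0.37), stellate cell markers (0.33) and pancreatic markers (-2.72). None of these 6 calls held with an estimated correlation (adjusted p = 0.241 to 0.889), and no member passed. Between fractions of wild-type liver the effect of tBuHQ differed for 13 genes, named ones being Rc3h2 (2.72), Ago2 (2.69, without an exact size, with a group mean of 12.7), Flt4 (2.59), Col14a1 (2.48), Adgrf5 (2.37), Larp4 (2.15) and Sys1 (-2.10). The preset correlation called it there for RIDD substrates (1.31), endothelial markers (0.81), proteasome (-0.24), immediate early (-0.27), ribosomal protein (-0.61) and oxidative phosphorylation genes (-0.84), and 0 of these 6 calls held with an estimated correlation (adjusted p = 0.436 to 0.759). Between fractions of knockout liver it was called for aminoacyl-tRNA synthetases (0.39), heat shock genes (0.27), the proteasome (0.18) and endothelial markers (-0.39), with an adjusted p of 0.559 to 0.981 with an estimated correlation and no member past any adjustment. The difference between genotypes of that difference was called for oxidative phosphorylation (0.74), ribosomal protein (0.55), immediate early (0.49), proteasome (0.44), stellate (-0.71), lipogenic (-0.85), endothelial (-1.28) and RIDD genes (-1.78), with an adjusted p of 0.438 to 0.689 with an estimated correlation and 0 genes called by limma, where 1532 had an unadjusted p under 0.05.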

How the results depend on the processing

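Removing each array's trend on gene span was chosen after seeing the data; the other alternatives were fixed before. Where an array was left out, the lone array of its group was assumed to vary like the other groups, and 2 arrays per group limited what could be called. Absent spike-in probe sets read up to 15.1, near the median signals of 17.1 to 22.9, so that dim genes could not be compared. Named genes were run with every alternative except the authors' z scores, by whose column names every tBuHQ difference would turn its sign. For the 224 called named genes 2821 values kept direction and call, 1132 kept direction and lost the call, and 0 reversed. For the 132 called lists these numbers were 1729, 298 and 5, and 129 of the 298 were lost with an estimated correlation. Lists were not run with the other offsets, the span trend removed, the pool as a random block (correlation 0.112) or the authors' z scores. Whether the list calls hold with the span trend removed was thus not tested. The cause of the changes below was not tested.

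The wild-type tBuHQ count of 518 in unfractionated RNA went to 298 with no filter, 270 and 267 with quantile normalization over all arrays and within each fraction, 1459 with only the arrays of the comparison, 321 with the span trend removed, 329 with the authors' z scores by column name (268 higher, 61 lower), and 1 to 35 with 1 array left out. The genotype difference of 645 went to 406 and 423 with quantile normalization, 1335 with only its arrays, 427 with z scores, and 0 to 1172 with 1 array left out. Knockout tBuHQ stayed at 0 except for 90 with 1 array left out (0 to 90). In polysome RNA the wild-type count of 2 went to 0 with only its arrays and 0 to 286 with 1 array left out, the knockout count stayed at 0 to 0, and their difference at 0 to 154.

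The wild-type shift between fractions, 13 genes, went to 0 with an offset of 1, 29 with an offset of 64, 2 with no filter, 37 with the 60th percentile filter, 0 with quantile normalization of either kind, 0 with all probe sets, 0 with eBayes without a trend, 126 with the pool block, 0 with the span trend removed, 0 with z scores and 0 to 540 with 1 array left out. With 1 array left out the knockout shift gave 0 to 0 and the 3-way difference 0 to 395. The untreated genotype difference of 849 went to 550 with no filter, 2839 with only its arrays, 0 with z scores, whose names swap the treatments, and 0 to 9 with 1 array left out. In polysome RNA, 1 gene went to 2 with quantile normalization over all arrays, 0 with median centring, 3 with only its arrays, 0 with z scores and 0 to 0 with 1 array left out.

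Between untreated wild-type fractions 73 genes went to 128 with an offset of 64, 42 with no filter, 135 with the 60th percentile filter, 167 with quantile normalization within fractions, 20 with median centring, 44 with eBayes without a trend, 211 with the pool block, 147 with only its arrays, 1856 with z scores and 0 to 14 with 1 array left out. In the knockout 1144 went to 1835 with all probe sets, 2273 with only its arrays, 102 with z scores and 122 to 463 with 1 array left out. The Perk target kept its direction from -1.62 to -0.83 over 27 alternatives, and from -1.43 to -1.19 with 1 array left out, where 3 arrays ended its call (adjusted p 0.00117 to 0.0626 over all).

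Reversed list medians were -0.11 and -0.10 for plasma proteins and -0.0947 and -0.0923 for P450 enzymes in wild-type unfractionated RNA with quantile normalization over all arrays and within fractions, and 0.0477 for ribosomal proteins in knockout unfractionated RNA without the first tBuHQ array (-0.43 without the second). Under both quantile normalizations camera called plasma proteins lower (adjusted p = 0.0188 and 0.0170) and did not call P450 enzymes. Quantile normalization moved the median of all genes by -0.16 and -0.15 for the genotype difference in unfractionated RNA, 0.12 and 0.12 for the 3-way difference and 0.13 and 0.13 for the untreated genotype difference. Median centring moved it by 0.13 between untreated wild-type fractions.

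With the replicate number as a block the 13 counts were 483, 0, 623, 2, 0, 0, 0, 0, 0, 774, 1, 72 and 1087, in the order of the report's comparisons, so the wild-type shift between fractions lost its 13 calls. The numbers were not taken to pair the arrays, since the labels do not say that they do and not every correlation passed 0.1: between fractions of the same genotype and treatment the differences of array 1 and array 2 correlated across genes at 0.0825 to 0.326, all above 0 and 2 of 4 over 0.1, and otherwise at -0.302 to 0.359, 7 of 24 over 0.1. The bound of 0.1 is not a test of pairing. The day-phase clock mean and 5 of 6 pancreatic markers did go together by number, so that a shared origin of some arrays is not excluded. With the pool as a random block the wild-type shift between fractions had 126 calls. Between the fractions of untreated wild-type and knockout liver there were then 211 and 1450 calls.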

Other observations

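These values were chosen after the data were seen, and no test was run on them.

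Cyp2c37 was high on all 4 arrays of wild-type liver with tBuHQ. It read 1883 and 1708 on the wild-type tBuHQ unfractionated arrays and 1754 and 464 on the polysome arrays, and 8.03 to 54.4 on the 12 other arrays. Its relatives spanned a smaller range. Cyp2c50 read 6767 and 7784 on the wild-type tBuHQ unfractionated arrays, 6446 and 2937 on the polysome arrays of that group and 1659 to 4174 on the 12 others. Cyp2c54 read 4724 and 3173, then 4057 and 1231, and 837 to 2816 on the 12 others.

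Of 6 pancreatic markers 5 (Cel, Cela2a, Cpa1, Ctrb1 and Prss2) read higher on the first wild-type tBuHQ and the first untreated knockout array of both fractions than on any of the other 12 arrays. Ctrb1, a chymotrypsinogen, read 699 and 555 on the first wild-type tBuHQ arrays (unfractionated and polysome) and 498 and 920 on the first untreated knockout arrays. The second arrays of those groups read 45.2 and 5.05, and 7.66 and 22.3. The elastase Cela1, at 745 or more on every array, did not follow them, with 876 on the first and 1868 on the second wild-type tBuHQ polysome array.

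Dbp read 1200 and 909 in unfractionated and polysome RNA on the first and 284 and 379 on the second wild-type tBuHQ arrays, and 1719 and 988 on the first and 538 and 273 on the second untreated knockout arrays. On the untreated wild-type arrays it read 60.8 and 74.3, then 45.3 and 64.4. The knockout tBuHQ arrays differed in unfractionated RNA, with 61.1 on the first and 325 on the second, but read 152 and 162 in polysome RNA.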
